A study of Rattus norvegicus with 4 samples.

How the data were processed

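RNA was measured by sequencing in 4 libraries of rat H9C2 cells, 2 controls and 2 treated with PAGln at 100 µM for 48 h. Per the labels' protocols, RNA was taken up in Trizol, libraries were made with a TruSeq RNA kit and sequenced on an Illumina instrument. Groups were taken from the treatment label of each sample and replicate numbers from its title. The labels give 2 different numbers of repeats for the design, and 2 libraries per group were analysed here.

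The deposited values are FPKM per gene, 1 table per library, made by the authors. The submitters' processing notes name Bowtie 0.12.2 and the genome build hg38, which is a human build, while the tables hold 32883 rat Ensembl gene identifiers and 895 further loci without an Ensembl identifier. The build behind the coordinates, the counting tool and the treatment of reads that match several loci are not given in the sources used here, nor is whether counting used the strand. Coordinates are printed as the deposited tables give them. Per the file headers each table holds a gene length, and in the values as deposited each gene's FPKM times its length is a whole multiple of 1 step per library. All non-zero values (100%) came out whole within 0.01 of a read. This gave the recovered reads per library, from 13507110 to 14984712, on the assumption that the smallest step is 1 read. FPKM are not counts, so the gene and list results rest on log2(FPKM + 1), and the recovered reads were tested only as an alternative (voom) and for counting error (exact binomial test). Alternatives set out beforehand for the case of deposited counts were not run.

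Genes with a mean of 1 FPKM or more over the 4 libraries were tested (12334, of which 10835 protein-coding). limma 3.58.1 in R 4.3.3 was fitted to log2(FPKM + 1) with eBayes and a variance trend, two-sided, with no covariate, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are PAGln minus control on the log2(FPKM + 1) scale, which understates the change of genes with low values. Errors are SD over 2 libraries for FPKM and SE from limma for log2 fold changes. A group total of 0 was set to a floor of 3 reads, which covers counting error in that total only.

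32 gene lists were fixed before the data were examined. They covered muscle, calcium and adrenergic genes, inflammation, stress, cell cycle, metabolism, translation and markers of other cell types. Of 1065 list entries, 999 matched a gene name in the tables, 21 matched through a RefSeq table of assembly GRCr8 used for names only, and 45 did not match. The 28 lists with 5 or more tested genes were compared with the other tested genes by limma's camera with a preset correlation of 0.01, two-sided and adjusted over the 28 lists, and members were also adjusted over the list alone. 25 tested genes belong to more than 1 list. Named genes followed a rule set at the same time. As no gene passed, the 5 genes with the smallest unadjusted p in each direction were named, leaving out automatic gene symbols. For a described list up to 4 members with the smallest p were given, and question genes on natriuretic peptides, adrenergic receptors, Toll-like receptor 4 and calcium release were given whether or not they passed. Some genes that these rules name are not reported here. For the description of the cells, the most abundant members of 6 lists were used. The locus on chromosome 17 with the smallest adjusted p, LOC100911417, Txndc15, Ndufa1, the chromosome 15 copy of Uchl3, Myod1, Tnnt2, Casq2, Cdh15 and Atp2a2 fall outside these rules and were chosen after their values were seen. So do the chromosome 17 copy of Impad1 and the genes Actc1, Myh6, Actn2 and Myog.

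A copy marker was given to 1448 tested genes, either for an automatic or contig name or for a description shared with another identifier. Reads of near-identical copies may have been split between loci by the authors' counting, so the levels of such genes are uncertain. Control 1 and control 2 differed by more than sampling noise (19.3 chi-square units per gene on the recovered reads), as did PAGln 1 and PAGln 2 (17.3), so each library counted as 1 replicate.

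The gene test was checked on 20 simulated data sets of 12334 genes, each with 200 genes changed by known amounts and variances drawn from the fitted prior. On these, 5.35% of calls were false, and 0.7%, 20%, 68.5% and 82.4% of genes changed 1.5-fold, 2-fold, 4-fold and 8-fold were called. The list test was checked in the same way on lists of 40 genes. It called 5% of lists shifted by 0.05 on the log2 scale, 55% of those shifted by 0.1 and 100% of those shifted by 0.2. Genes varied independently in both checks. They therefore do not cover correlation between genes, estimated at 0.22 for the mitosis list and 0.27 for the cholesterol list. Nor do they cover the resemblance of libraries across the groups, so the rates may not hold for these libraries.

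Alternatives planned before the data were examined were a pseudocount of 0.1, no filter on low values, a mean of 5 FPKM, median-ratio scaling, quantile normalization, the replicate number as a block, leaving out each library, eBayes without a trend, robust eBayes, a fold of 1.5 or more, an adjusted p under 0.1, camera with an estimated correlation and fry. Alternatives added after seeing the data were limma's voom on the recovered reads, a minimum of 10 recovered reads on average, a block pairing control 1 with PAGln 2 and control 2 with PAGln 1, a loess correction for gene length with a span of 0.5, and camera with a variance trend. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.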

Results

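RNA was sequenced from H9C2, a cell line derived from embryonic rat heart that keeps many features of skeletal myoblasts, after 48 h with or without PAGln at 100 µM. PAGln is phenylacetylglutamine, a metabolite made in the body by joining glutamine to phenylacetate, which gut bacteria produce. There were 4 libraries, 2 from control cells and 2 from PAGln-treated cells. The labels do not say whether the libraries of a group came from separate cultures. The limma p-values of single genes therefore measure the spread between these libraries, which may be technical. Camera's p-values compare a list's genes with the other tested genes and depend on the correlation assumed between genes. With an estimated correlation they also rest on the few libraries, and all 28 lists then had an adjusted p from 0.968 to 0.972. The interferon list's camera p rose from 0.103 to 0.216, though its estimated correlation of -0.043 lay under the preset 0.01. A call lost under that setting is therefore not shown to rest on correlation. The exact binomial and Fisher tests do not measure the spread between libraries. The FPKM values correspond to 14934592 reads in control 1, 14984712 in control 2, 13507110 in PAGln 1 and 13585802 in PAGln 2. For a transcript of 1 kb, 1 read was worth 0.0671 FPKM in control 1, 0.0663 in control 2, 0.0738 in PAGln 1 and 0.0732 in PAGln 2. Of 33778 gene identifiers, 12334 reached a mean of 1 FPKM over the 4 libraries and were tested.

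The cells expressed some striated muscle genes together with most smooth muscle markers and some fibroblast markers. Of the smooth muscle and pericyte identifiers, 11 of 13 reached the filter, with Tagln at a mean of 994 FPKM. Acta2, smooth muscle actin, had a mean of 3843 FPKM over the 4 libraries (range 3161 to 4147), and Ankrd1, a stretch-responsive cardiac ankyrin repeat protein, had a mean of 1144 FPKM (range 1031 to 1208). Among sarcomere genes the tropomyosins Tpm2 (481 FPKM) and Tpm1 (399 FPKM) were the most abundant, and cardiac troponin T, Tnnt2, had a mean of 157 FPKM. 14 of the 32 sarcomere identifiers and 11 of the 20 hypertrophy and fetal identifiers reached the filter. Other genes of these lists lay far under it, such as Actc1 (0.011 FPKM), Myh6 (0.16 FPKM) and Actn2 (0.053 FPKM). The myogenic regulator Myod1 had a mean of 40.5 FPKM, the integrin Itga7 188 FPKM and the cadherin Cdh15 91.2 FPKM, while the regulator Myog had 1.33 FPKM. Of the calcium handling genes, Casq2, cardiac calsequestrin, had a mean of 238 FPKM and Atp2a2, the sarcoplasmic reticulum calcium pump, 114 FPKM. 5 of the 13 fibroblast identifiers reached the filter, of which Thy1 had a mean of 348 FPKM, S100a4 231 FPKM and Pdgfrb 92.1 FPKM. Few markers of unrelated cell types reached the filter: 2 of 14 endothelial, 2 of 16 macrophage and leukocyte, 1 of 13 epithelial, and 2 of 12 neural and glial identifiers. The most abundant of these were Flt1 (13.2 FPKM), Cd14 (15.9 FPKM), Krt8 (29.9 FPKM) and Ncam1 (109 FPKM), the last of which myoblasts also express.

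The comparison of PAGln-treated with control cells asks which transcripts differ in abundance in these cells after 48 h with the metabolite. Genes of mitosis ranked higher in the PAGln libraries, with 39 of 47 members higher and a median log2 fold change of 0.068, a shift carried by PAGln 2 (camera adjusted p = 0.0191, and adjusted p = 0.968 with an estimated correlation). Genes of cholesterol synthesis and uptake ranked lower, with 21 of 24 members lower and a median log2 fold change of -0.066, carried by PAGln 1 (camera adjusted p = 0.0304, and adjusted p = 0.968 with an estimated correlation). No single gene passed the threshold. Nqo1, a quinone reductase induced through NRF2 and the aryl hydrocarbon receptor, was among the 5 named genes with the smallest p on the lower side, at 77.5 ± 4.79 FPKM in control and 55.4 ± 0.822 FPKM in PAGln libraries (SD, n = 2 each). Of the 165 genes with a log2 fold change beyond 1 either way, 81 were small RNA genes with few reads and 68 were protein-coding, 44 of these with a copy marker by name or description. Splits other than treatment gave about as many such genes. Control 1 and PAGln 2 against control 2 and PAGln 1 gave 188, and replicates 1 against replicates 2 gave 152.

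Of the 12334 genes tested with limma on log2(FPKM + 1), 0 had an adjusted p under 0.05, and 262 had an unadjusted p under 0.05 (136 higher and 126 lower with PAGln), where 617 would be expected by chance. limma's voom on the recovered read numbers also called 0 genes and gave 134 at an unadjusted p under 0.05. A block pairing control 1 with PAGln 2 and control 2 with PAGln 1, chosen after seeing the data, gave 0 and 899. The count of 262 thus depends on the spread left in the fit and does not show that the groups differ less than by chance. The 2 PAGln libraries lay on one side of both control libraries for 2847 genes, or 23.1%, where chance gives 33.3%. The smallest adjusted p was 0.0892, for an unannotated locus on chromosome 17 from 8982584 to 8984427 whose product the files match to thioredoxin domain-containing protein 15. It had 12.5 ± 1.89 FPKM in control and 0.244 ± 0.0701 FPKM in PAGln libraries, while the annotated Txndc15 gene had 29.2 ± 6.68 and 25.2 ± 5.29 FPKM, a direction that turned without control 2 and without PAGln 2. The locus passed under limma with a minimum of 10 recovered reads (adjusted p = 0.0320) and with a correction for gene length (adjusted p = 0.0467), both chosen after seeing the data, and without PAGln 1 (adjusted p = 0.0215) or PAGln 2 (adjusted p = 0.0116). The 95% confidence interval of a gene's log2 fold change had a median half-width of 0.40. In simulated data the test called 0.7% of genes changed 1.5-fold, 20% of those changed 2-fold, 68.5% of those changed 4-fold and 82.4% of those changed 8-fold. Variances there were drawn from the fit, 200 genes were changed and genes varied independently, so these rates may not hold for these libraries. Leaving out a library gave 2 genes without control 1, 1 without control 2, 5 without PAGln 1 and 13 without PAGln 2, the lone library of a group then being assumed to vary like the other group.

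The 5 named genes with the smallest p on the higher side did not pass the threshold. Atp5pb, a subunit of the mitochondrial ATP synthase on chromosome 2 from 208566385 to 208577146, had 1.20 ± 0.102 FPKM in control and 17.04 ± 5.94 FPKM in PAGln libraries. Its log2 fold change was 2.999 (SE 0.26, limma adjusted p = 0.266). A second locus on chromosome 2 annotated as a like protein, LOC100911417, went the other way, with 14.4 ± 0.716 FPKM in control and 5.31 ± 6.60 FPKM in PAGln libraries (9.98 in PAGln 1 and 0.639 in PAGln 2). Uchl3, a ubiquitin hydrolase, is annotated at 2 loci. The chromosome 3 copy (171092946 to 171134655) had 0.145 ± 0.0694 FPKM in control and 4.25 ± 1.07 FPKM in PAGln libraries (limma adjusted p = 0.459), and the chromosome 15 copy had 18.2 ± 13.6 and 4.91 ± 3.55 FPKM. Gstm3, a glutathione transferase on chromosome 2 (210685197 to 210688272), had 0.417 ± 0.292 FPKM in control and 18.1 ± 12.6 FPKM in PAGln libraries, with 27.0 in PAGln 1 and 9.17 in PAGln 2. Impad1, a nucleotide phosphatase on chromosome 5 (17633766 to 17663589), had 0.622 ± 0.0870 and 7.01 ± 3.46 FPKM. Rps19l2, a copy of the gene of ribosomal protein S19 on chromosome 9 (16802319 to 16807966), had 58.9 ± 18.6 and 146 ± 10.5 FPKM, and Rps19 itself had 192 ± 37.7 and 111 ± 32.8 FPKM. Reads of such copies can be assigned to either locus, so the level of each is uncertain. For Impad1 the other annotated locus, on chromosome 17, had 1 read in control 2 and 0 in control 1, PAGln 1 and PAGln 2. Atp5pb passed under limma without PAGln 2 (adjusted p = 0.0116), as did Gstm3 (adjusted p = 0.0116).

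The 5 named genes on the lower side did not pass either. Nhp2, a protein of the snoRNA-guided pseudouridylation complex on chromosome 10 (34975708 to 34979082), had 26.4 ± 15.6 FPKM in control and 0.663 ± 0.160 FPKM in PAGln libraries, with 15.3 in control 1 and 37.4 in control 2. Its log2 fold change was -3.92 (SE 0.41, limma adjusted p = 0.446; 0.0485 without control 1). Ntan1, an amidase of the N-end rule pathway on chromosome 10 (3218466 to 3235229), had 7.21 ± 1.24 and 2.70 ± 0.0144 FPKM, a log2 fold change of -1.14 (SE 0.17). The microRNA gene Mirlet7i, on chromosome 7 from 66802732 to 66802821, had 3 and 5 reads in the control libraries and 0 in both PAGln libraries. With the PAGln total set to a floor of 3 reads, the control total was 2.41-fold higher. This ratio takes no account of error in the few control reads and is not a lower limit. Mirlet7d, on chromosome 17 from 16419980 to 16420077, had 10 and 11 reads in control and 4 and 5 in PAGln libraries. Nqo1, on chromosome 19 from 38422164 to 38437180, had 1902 and 1765 reads in control and 1198 and 1182 in PAGln libraries. Its log2 fold change was -0.48 (SE 0.10, 95% confidence interval -0.73 to -0.22).

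**Figure D1:**
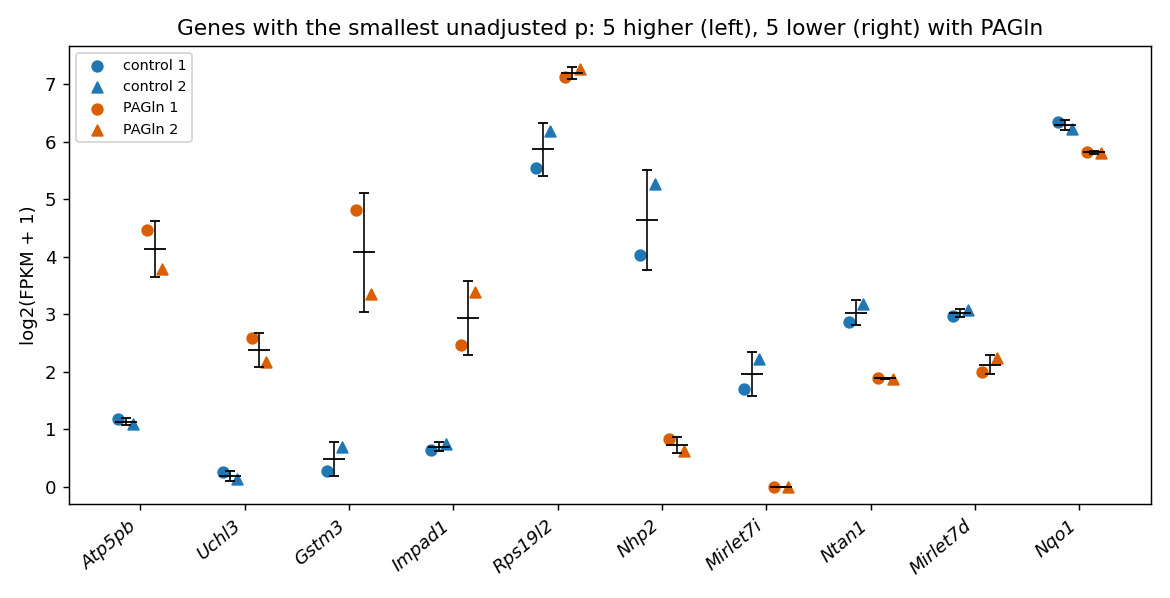
Expression of the 10 named genes in each library as log2(FPKM + 1), with control libraries in blue and PAGln libraries in orange; black bars give the mean and SD of the 2 libraries of a group. Nqo1 lies near 77.5 FPKM in control and 55.4 FPKM in PAGln libraries, and the 5 genes on the left include copies whose FPKM was under 1 in both control libraries, such as Gstm3.

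Mitosis genes and cholesterol genes were the 2 of 28 tested gene lists that passed camera with a preset correlation of 0.01. For mitosis the adjusted p was 0.0191, and it was 0.968 with an estimated correlation. No member passed over all genes or adjusted over the list alone. Cks2, a subunit of cyclin-dependent kinase complexes, had 36.7 ± 2.17 FPKM in control and 44.4 ± 2.80 FPKM in PAGln libraries, a log2 fold change of 0.27 (SE 0.11). The spindle checkpoint genes Mad2l1 and Ttk had log2 fold changes of 0.20 (SE 0.12) and 0.26 (SE 0.19), and the centrosomal kinase Nek2 had 0.20 (SE 0.14). The mean of the mitosis list lay 0.11 above its 4-library mean in PAGln 2 and 0.047, 0.034 and 0.027 below it in control 1, control 2 and PAGln 1, on the log2 scale. Without PAGln 2 the median log2 fold change of the mitosis list was 0.012 (camera adjusted p = 0.887), and without control 1 it was 0.061 (camera adjusted p = 0.348). Genes of S phase and DNA replication did not pass (29 of 39 higher, camera adjusted p = 0.332), but did without control 2 (camera adjusted p = 0.00142, and adjusted p = 0.907 with an estimated correlation). Of these, Orc1, the largest subunit of the origin recognition complex, had 3.47 ± 0.0794 and 5.02 ± 0.332 FPKM, Tyms had 12.4 ± 0.289 and 13.97 ± 0.0745 FPKM, and Tk1, thymidine kinase, had 27.6 ± 0.920 and 23.7 ± 1.30 FPKM.

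For cholesterol synthesis and uptake the camera adjusted p was 0.0304, and it was 0.968 with an estimated correlation. No member passed over all genes or adjusted over the list alone. Acat2, the cytosolic thiolase, had 74.1 ± 0.716 FPKM in control and 59.3 ± 6.07 FPKM in PAGln libraries, a log2 fold change of -0.32 (SE 0.11). Mvk, mevalonate kinase, had 33.8 ± 1.32 and 29.1 ± 1.51 FPKM, Tm7sf2, a sterol reductase, had 21.7 ± 3.46 and 17.6 ± 1.19 FPKM, and Dhcr7, which makes the last step to cholesterol, had 54.8 ± 0.259 and 48.3 ± 6.51 FPKM. The list's mean lay at -0.12 from its 4-library mean in PAGln 1 and at 0.061, 0.036 and 0.027 in control 1, control 2 and PAGln 2. The median log2 fold change was -0.0017 without PAGln 1 (camera adjusted p = 0.744) and -0.032 without control 1 (camera adjusted p = 0.348). With quantile normalization the list did not pass (camera adjusted p = 0.128).

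**Figure D2:**
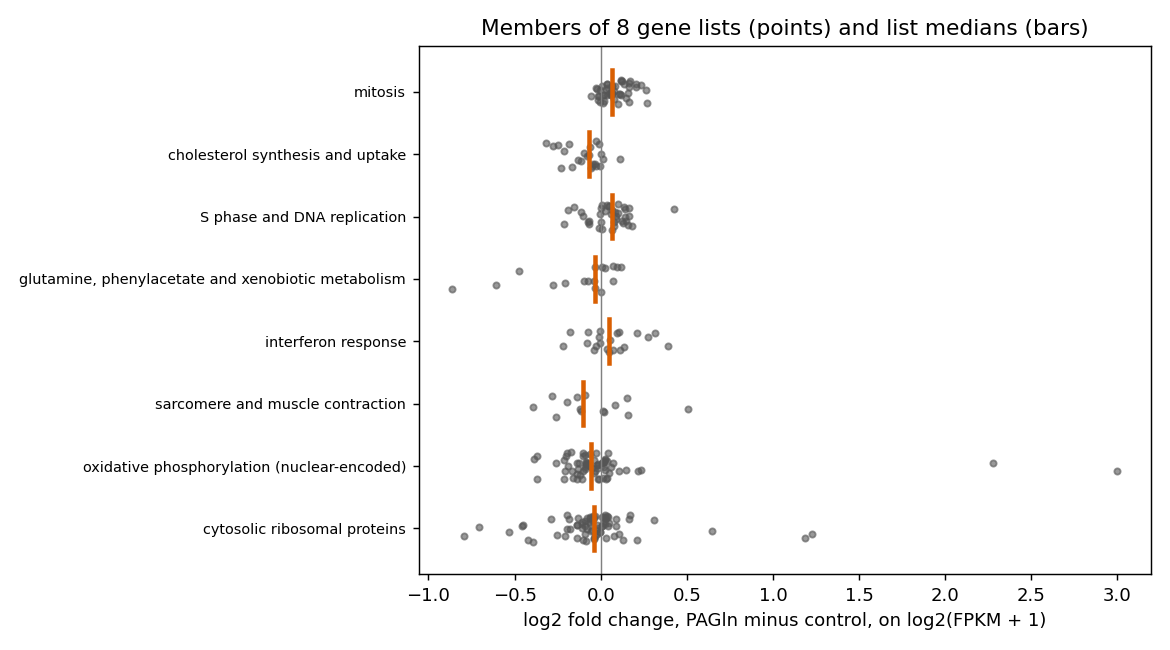
Log2 fold changes (PAGln minus control, on log2(FPKM + 1)) of the tested members of 8 gene lists as points, with each list's median as a bar. The mitosis median lies at 0.068 and the cholesterol median at -0.066, and the points far to the right include Atp5pb (2.999) and Ndufa1 (2.28, and -0.60 without PAGln 1) in the oxidative phosphorylation list and the chromosome 5 copy of Rps27a (1.22) in the ribosomal list.

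Genes of glutamine, phenylacetate and xenobiotic metabolism, the list closest to the metabolite itself, did not pass (10 of 17 lower, camera adjusted p = 0.332). Without control 2 it passed as lower (camera adjusted p = 0.0173, and adjusted p = 0.907 with an estimated correlation). Cyp1b1, a cytochrome P450 induced by the aryl hydrocarbon receptor, had 97.6 ± 47.2 FPKM in control and 50.5 ± 9.76 FPKM in PAGln libraries, with 131 in control 1 and 64.3 in control 2. Ahrr, the repressor of that receptor, had 18.2 ± 6.54 and 11.4 ± 2.25 FPKM. Glul, glutamine synthetase, had 37.5 ± 0.0922 and 32.4 ± 1.19 FPKM, a log2 fold change of -0.21 (SE 0.10, limma adjusted p = 1.00). Oxidative stress genes and NRF2 targets had 18 of 29 members lower (camera adjusted p = 0.705), with Nqo1 lower and Gclm, a subunit of the glutathione-synthesis enzyme, at 18.9 ± 0.456 and 20.99 ± 0.972 FPKM.

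Of the genes for which the metabolite has been studied in cardiac cells, Tlr4, Il6 and Camk2d were tested, and none passed the threshold. Tlr4, a receptor for bacterial lipopolysaccharide, had 6.56 ± 1.47 FPKM in control and 7.73 ± 0.659 FPKM in PAGln libraries, and the cytokine Il6 had 6.38 ± 0.303 and 7.07 ± 0.111 FPKM. Their log2 fold changes were 0.22 (95% confidence interval -0.25 to 0.69) and 0.13 (-0.20 to 0.46). Camk2d, the calcium/calmodulin-dependent kinase, had 54.0 ± 5.19 and 57.4 ± 2.57 FPKM, a log2 fold change of 0.088 that was -0.0084 without control 2. The genes that follow lay under the filter. The alpha-adrenergic receptor Adra2a had 11 reads in control and 10 in PAGln libraries, and Adrb1 had 0 reads in all 4 libraries. Nppb, the gene of brain natriuretic peptide, had 11 reads in control and 18 in PAGln libraries, of which 14 were in PAGln 1. Nppa had 0 and 2 reads and the myosin heavy chain Myh7 had 3 and 5. Ryr2, the cardiac ryanodine receptor, had 10 reads in control, 9 of them in control 2, and 0 with PAGln. As their means lay under 1 FPKM, none of these genes was tested.

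Muscle and signalling lists did not pass camera with all 4 libraries. In the sarcomere list 8 of 14 members were lower (adjusted p = 0.705), and it passed as lower without PAGln 1 (camera adjusted p = 0.0183, and adjusted p = 0.895 with an estimated correlation). Of its members, Mylpf, a fast skeletal myosin light chain, had 2.74 ± 0.362 FPKM in control and 4.33 ± 0.734 FPKM in PAGln libraries while Myl4 had 8.64 ± 0.634 and 6.52 ± 2.45 FPKM. Of the hypertrophy and fetal genes 6 of 11 were lower (adjusted p = 0.942), of the myogenic genes 7 of 12 (adjusted p = 0.733) and of the calcium handling genes 14 of 25 (adjusted p = 0.733). Of the calcium handling genes, Itpr1, a calcium release channel, had 8.90 ± 1.68 and 9.97 ± 0.570 FPKM, its log2 fold change of 0.16 being -0.015 without control 2. For adrenergic receptor and cAMP signalling 14 of 26 were higher (adjusted p = 0.760), with the kinases Grk5 at 21.9 ± 1.42 and 19.6 ± 0.470 FPKM and Grk6 at 14.9 ± 0.865 and 13.1 ± 1.27 FPKM.

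Inflammatory, stress and matrix lists did not pass camera. Toll-like receptor and NF-kB genes had 13 of 22 members higher (adjusted p = 0.705) and interferon response genes 12 of 21 (adjusted p = 0.449). Of the interferon genes, Rtp4 had 1.59 ± 0.0345 FPKM in control and 2.23 ± 0.0928 FPKM in PAGln libraries and Ddx58, the RNA sensor RIG-I, had 3.70 ± 0.428 and 4.67 ± 0.0910 FPKM. In the extracellular matrix list 26 of 40 members were lower (adjusted p = 0.509). Col5a3 had 4.97 ± 0.146 and 3.63 ± 0.182 FPKM, and Col1a2 had 417 ± 33.7 and 622 ± 296 FPKM, with 831 in PAGln 2 and a log2 fold change of -0.010 without that library. Of p53 targets 18 of 30 were lower (adjusted p = 0.509), and Plk3 had 9.61 ± 0.126 and 7.63 ± 0.916 FPKM. Of immediate early genes 20 of 27 were lower (adjusted p = 0.449), and Jun had 43.9 ± 2.44 and 37.8 ± 0.841 FPKM. The secretory factors of senescence had 12 of 17 members lower (adjusted p = 0.675), YAP/TEAD targets 11 of 22 (adjusted p = 0.749), autophagy and lysosome genes 23 of 40 (adjusted p = 0.733), and fatty acid oxidation genes 13 of 24 (adjusted p = 0.509). Fibroblast markers had 4 of 5 members lower (adjusted p = 0.509) and smooth muscle and pericyte markers 8 of 11 (adjusted p = 0.509).

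Energy metabolism and ribosomal lists did not pass camera with all 4 libraries. Gene length had a Spearman rho of 0.14 with PAGln minus control over the 12334 tested genes. The median length was 739.5 bases in the oxidative phosphorylation list and 703 in the ribosomal list. Without control 1 the oxidative phosphorylation and ribosomal lists passed as lower (camera adjusted p = 0.000120 for both, and adjusted p = 0.845 with an estimated correlation). Without control 2 they passed as higher (camera adjusted p = 0.0173 and 0.0442, and adjusted p = 0.907 with an estimated correlation). Without PAGln 1 they passed as lower and the mitochondrially encoded transcripts as higher (camera adjusted p = 0.00102 for each, and adjusted p = 0.895 with an estimated correlation). Of the nuclear genes of oxidative phosphorylation 44 of 66 were lower (adjusted p = 0.449), and Atp5pb was the 1 member that passed when adjusted over the list alone; in the other lists 0 members did, and over all genes tested 0 members of any list passed. Of the mitochondrially encoded transcripts 11 of 13 were higher (adjusted p = 0.509), with ND4 at 246 ± 8.97 FPKM in control and 356 ± 84.1 FPKM in PAGln libraries. Of the ribosomal protein identifiers 47 of 73 were lower (adjusted p = 0.449), and 33 of the 73 carry a copy marker, given by name or description and not by sequence. Rps27a is listed at 2 loci, of which the chromosome 5 copy had 210 ± 12.98 and 516 ± 223 FPKM and the chromosome 14 copy 720 ± 77.5 and 449 ± 131 FPKM. Glycolysis and hypoxia genes had 21 of 31 members lower (adjusted p = 0.760), ATF4 and amino acid response genes 16 of 33 (adjusted p = 0.942), protein folding genes of the unfolded protein response 16 of 29 (adjusted p = 0.942) and heat shock genes 7 of 20 (adjusted p = 0.705). The median and the mean log2 fold change of a list differed in sign for oxidative phosphorylation (-0.056 and 0.016), glycolysis and hypoxia (-0.043 and 0.018), heat shock (0.046 and -0.023), adrenergic signalling (0.0066 and -0.013), ATF4 (0.0063 and -0.00079) and protein folding (-0.0069 and 2.6e-05). Camera's direction followed the median for oxidative phosphorylation, glycolysis, heat shock and ATF4, and the mean for adrenergic signalling and protein folding.

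The spread between replicates was as large as the difference between groups. Pearson's r of log2(FPKM + 1) across the tested genes, which are not independent replicates, was 0.975 between the control libraries and 0.975 between the PAGln libraries. It was 0.981 between control 1 and PAGln 2, 0.980 between control 2 and PAGln 1, 0.976 between control 1 and PAGln 1 and 0.971 between control 2 and PAGln 2. The first principal component held 45.5% of the variance and placed control 1 (-14.0) and PAGln 2 (-20.9) opposite control 2 (21.8) and PAGln 1 (13.1). The groups were apart on the second component, which held 29.9%, with control 1 at -12.6, control 2 at -14.5, PAGln 1 at 20.8 and PAGln 2 at 6.35. Ribosomal protein genes followed the first component, with list means of -0.10 in control 1, 0.14 in control 2, 0.11 in PAGln 1 and -0.15 in PAGln 2. The nuclear genes of oxidative phosphorylation lay at -0.15, 0.13, 0.16 and -0.15 in the same order, and the mitochondrially encoded transcripts at 0.081, -0.14, -0.19 and 0.25. With 2 libraries against 2, an exact two-sided permutation test of a single value cannot give a p below 0.333.

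**Figure D3:**
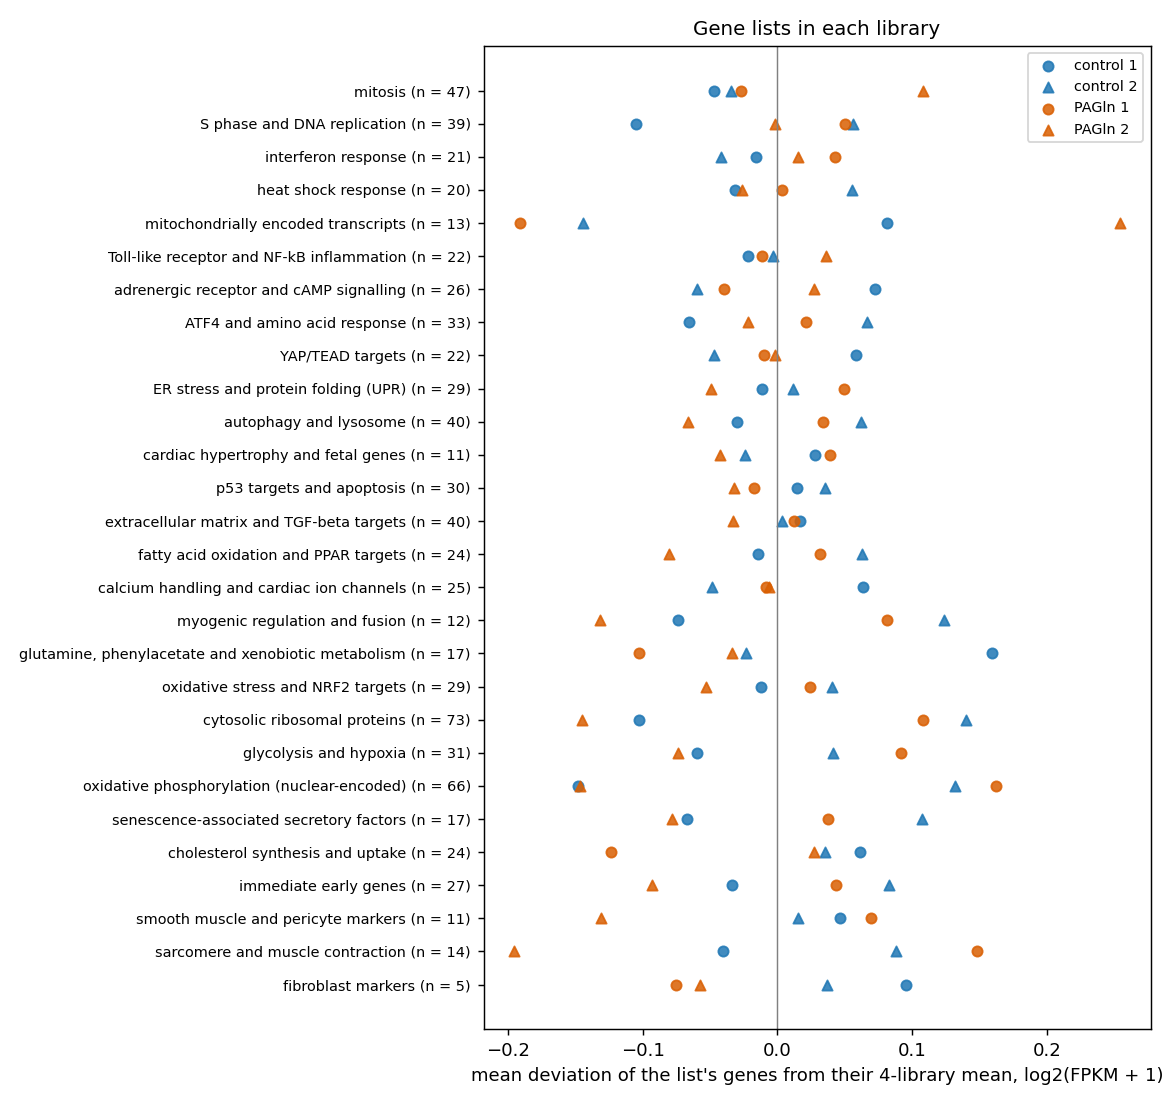
Mean deviation of each of the 28 gene lists from its 4-library mean in each library, in log2(FPKM + 1), with control libraries in blue, PAGln libraries in orange, circles for replicate 1 and triangles for replicate 2. Lists are ordered by the median log2 fold change of their members. Oxidative phosphorylation genes lie near -0.15 in control 1 and PAGln 2, and the mitosis list lies at 0.11 in PAGln 2 alone.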

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

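The voom fit, the minimum of 10 recovered reads, the crossed pairing, the gene length correction and camera's variance trend were chosen after seeing the data. Alternatives that need deposited counts were not run. The count of 0 genes held with a pseudocount of 0.1, no filter, a mean of 5 FPKM, both scalings, eBayes without a trend, robust eBayes, a fold of 1.5 or more, voom and the crossed pairing. It became 1 with an adjusted p under 0.1, 1 with a minimum of 10 recovered reads and 1 with the gene length correction, in each case the chromosome 17 locus described with the gene tests. Leaving out 1 library gave 1 (without control 2) to 13 genes (without PAGln 2), and the cause was not tested.

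The count of 2 lists became 1 with quantile normalization, where the cholesterol median was -0.051. It became 0 with an estimated correlation and 0 with fry, the medians of 0.068 for mitosis and -0.066 for cholesterol being unchanged since only the test differed. Leaving out 1 library gave 1 list (without PAGln 2) to 6 lists (without control 2). The mitosis median then ran from 0.012 (without PAGln 2) to 0.16 (without PAGln 1), and the cholesterol median from -0.16 (without PAGln 2) to -0.0017 (without PAGln 1). The camera adjusted p over all these alternatives ran from 0.00102 to 0.968 for mitosis and from 0.00174 to 0.968 for cholesterol, with fry at 0.969 for both.

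With the replicate block, 7 genes (3 higher and 4 lower) and 0 lists passed, among the genes Atp5pb, Nhp2 and the chromosome 17 and 20 loci (adjusted p = 0.0151 each, limma), the lists with medians of 0.068 and -0.066 and adjusted p of 0.157 and 0.169. The labels do not say that a number marks a shared culture or day, and same-numbered libraries deviated from their group means in opposite directions (r = -0.28 across 12334 genes). Under the crossed pairing 0 genes and 2 lists passed, with 899 genes at an unadjusted p under 0.05 (limma), where 617 would be expected by chance.

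Of the 73 genes followed singly through the alternatives, 7 turned direction, each when 1 library was left out. Log2 fold changes then ran from -0.0084 to 0.18 for Camk2d, from -0.015 to 0.33 for Itpr1, from -0.010 to 0.996 for Col1a2, from -0.67 to 0.12 for Tiparp, from -0.43 to 0.025 for Txndc15, from -1.04 to 3.41 for Rplp2 and from -0.60 to 5.15 for Ndufa1, and the cause was not tested. Of the 1297 values of these genes under the alternatives, 18 passed the threshold of their own setting. These include the chromosome 17 locus under the looser threshold of 0.1, at a limma adjusted p of 0.0892. Scaling moved the median log2 fold change of all tested genes from 0.0021 to 0.0019 (median ratio) or 0.0060 (quantile). At 13507110 to 14984712 reads per library, 488 tested genes had under 10 reads on average. Whether counting error or the spread between libraries sets the limit for such genes or for abundant ones was not compared.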

Other observations

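The test of copy markers, the count of the crossed split and the count of small RNA genes able to pass were chosen after their results were seen. The genes of the first and second paragraphs were also chosen after their values were seen.

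Cyp1b1, Ahrr, Tiparp and Nqo1, which respond to the aryl hydrocarbon receptor, a sensor of aromatic compounds, had lower mean levels in the PAGln libraries, and none passed the gene test. They were picked for being lower, so their shared direction is no test of the receptor. Ugt1a1, which also responds to it, had a log2 fold change of 0.12, and the list of glutamine, phenylacetate and xenobiotic metabolism did not pass (camera adjusted p = 0.332, 7 of 17 members higher). Cyp1b1 had 131 and 64.3 FPKM in the control libraries and 43.6 and 57.4 FPKM in the PAGln libraries. Ahrr had 22.9 and 13.6 FPKM in control and 9.78 and 12.96 FPKM with PAGln. Tiparp had 26.4 and 14.8 FPKM in control and 14.6 and 17.9 FPKM with PAGln. Nqo1 had 80.9 and 74.1 FPKM in control and 55.97 and 54.8 FPKM with PAGln. The receptor gene Ahr had 19.5 ± 0.635 FPKM in control and 22.05 ± 2.03 FPKM in PAGln libraries (SD, n = 2 each). Control 1 was the highest library for these 4 genes, and without it the log2 fold change of Tiparp was 0.12. Cyp1a1 had 2 reads in control and 1 in PAGln libraries.

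Several loci differed many-fold between libraries. An unannotated locus on chromosome 20 (19481408 to 19485846), matched in the files to subunit 4 of NADH dehydrogenase, had 592 and 239 FPKM in the control libraries and 29.3 and 29.97 FPKM in the PAGln libraries, while the mitochondrial gene ND4 had 239, 252, 297 and 416 FPKM in control 1, control 2, PAGln 1 and PAGln 2. Ndufa1, another subunit of that enzyme, had 71.7 FPKM in PAGln 1 and 0.344 to 1.56 FPKM in the other libraries. Rplp2, a ribosomal stalk protein, had 365 FPKM in PAGln 1 and 15.8 to 35.7 FPKM in the others. Summed over both Rps27a loci, reads scaled to CPM were 432, 478, 537 and 453 in the same order of libraries, a log2 ratio of PAGln to control of 0.12. For Rps19 with Rps19l2 the ratio of the sums was -0.0066, but for both Uchl3 loci it was -1.17, for Atp5pb with LOC100911417 0.52, for ND4 with the chromosome 20 locus -0.63, for Ndufa1 with LOC108348144 1.27 and for Pdcd5 with NEWGENE_1310561 0.85. Of these 7 sums, Rps27a and Rps19 lay nearest 0. In the same order of libraries, the Atp5pb sum was 31.1, 33.2, 64.6 and 27.97 CPM, above both controls in PAGln 1 only. The Ndufa1 sum was 10.98, 0.801, 15.5 and 13.03 CPM and the Pdcd5 sum 16.8, 1.20, 12.4 and 20.2 CPM, both far lowest in control 2. The Uchl3 sum was 7.97, 25.6, 10.3 and 4.64 CPM, highest in control 2. For ND4 (1002.5, 624, 444 and 610 CPM) and Ndufa1, both PAGln libraries lay on one side of both controls.

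Large fold changes were most frequent at 2 kinds of gene. The labelled groups gave 165 genes with a log2 fold change beyond 1 either way. Control 1 and PAGln 2 against control 2 and PAGln 1 gave 188, and replicates 1 against replicates 2 gave 152. Of the 68 protein-coding genes with a log2 fold change beyond 1 either way, 44 (64.7%) had a copy marker, against 8.78% of the other 10767 (Fisher's exact test, odds ratio 19.05, 95% interval 11.3 to 32.9, p = 1.31e-29). Counting noise alone was argued against for these genes, since 65 of them (95.6%, exact 95% interval 87.6% to 99.1%) differed beyond counting error between the groups (exact binomial test). They were selected for a difference between the same groups, however, and 55 of the 68 had enough reads to pass at a 2-fold difference. For these 55 a pass was largely set by the selection. Of the 81 small RNA genes with such a fold change, with a median of 3 reads per library, only 7 (8.64%) differed beyond counting error. However, 0 of the 81 had enough reads to pass at a 2-fold difference. For the small RNA genes other than these 7, counting noise and a real difference therefore cannot be told apart. For the 7, as for the 65, the test left out the spread between libraries. Reads shared between near-identical copies are therefore a candidate explanation for the protein-coding part, and an effect of PAGln on these loci stays open, as untested.

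Libraries resembled each other across the groups, control 1 with PAGln 2 and control 2 with PAGln 1. Splitting the 4 libraries in this way gave 1 gene at a limma adjusted p under 0.05, against 0 for the labelled groups and 1 for replicates 1 against replicates 2. At an unadjusted p under 0.05 it gave 2896 genes against 262 and 184. With the preset correlation it gave 11 lists (cholesterol among them, camera adjusted p = 0.0465) against 2 and 1 (mitosis, camera adjusted p = 0.0117). The 11 lists and the 1 were not tested with an estimated correlation. Under it the 2 labelled calls were lost, but all 28 lists then had a camera adjusted p from 0.968 to 0.972. That setting could hardly call any list with 4 libraries, so the loss decides nothing. The counts by split describe a structure of the samples other than the labelled groups. They restate the resemblance from which the crossed split was taken and are no separate support for it. Across genes, length had a Spearman rho of 0.33 with this crossed difference, yet after a correction for gene length the correlation of same-numbered deviations was -0.25 (bootstrap interval over genes -0.29 to -0.20), and without copy-marked genes it was -0.34 (-0.39 to -0.28), which argues against either alone as the whole cause; with both steps it was -0.29, a value without a computed interval. An exchange of a control and a PAGln library and a batch shared by the crossed pairs would both give this result and cannot be told apart, since the labels name no batch and, with 3 splits, a share under 0.05 cannot be reached.

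The mitosis and cholesterol lists, which passed camera with a preset correlation but had an adjusted p of 0.968 with an estimated correlation, were weighed against gene length bias. Across tested genes, length had a Spearman rho of 0.14 with PAGln minus control. After the correction for gene length their median log2 fold changes were 0.070 (bootstrap interval over genes 0.034 to 0.093) and -0.089 (-0.15 to -0.036). Both intervals lay beyond the bound set beforehand at 50% of the uncorrected values, but only narrowly. The bootstrap took genes as independent, so the intervals may be too narrow. Neither median shrank from its uncorrected value of 0.068 or -0.066, which argues against length as the cause. Each list's difference rested on a different PAGln library, PAGln 2 for mitosis and PAGln 1 for cholesterol, and both lists also passed in a split other than treatment, mitosis for replicates 1 against 2 (camera adjusted p = 0.0117, against 0.0191 for the labelled groups) and cholesterol for the crossed split (0.0465, against 0.0304). The labelled calls are therefore not evidence that sets PAGln apart from a difference between single libraries, and both stay open.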
